A study of Arabidopsis thaliana with 6 samples.

How the data were processed

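The data are small RNAs recovered from AGO1 immunoprecipitates of unopened flower buds of Arabidopsis thaliana Columbia-0, 3 libraries of WT and 3 of ddm1F6, described as biological replicates in the series description. Per the labels' protocols, plants grew side by side on soil in 18 h days at 23 °C, soluble protein was immunoprecipitated overnight with a polyclonal AGO1 antibody, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq kit. The labels do not expand the F6 in ddm1F6, and it is used here as given. The deposited files hold, for each library, the raw read count of every distinct small RNA sequence, with no header and no normalization. The submitters' processing notes name Bowtie, with no version, and TAIR10, and give no adapter trimming, filter or matching rule. The deposited totals were 6721927, 7302770 and 1795708 reads for WT and 2290767, 3091307 and 3010078 for ddm1F6, over sequences of 16 to 28 nt. Reads of 18 to 28 nt were used, 1468619 distinct sequences, and the few of 16 and 17 nt were left out of the comparisons.

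Every deposited sequence, 1505061 in all, was searched for perfect matches in the TAIR10 reference genome with a search written in python 3.11.15 (numpy 2.4.6, numba 0.67.0), and each had at least 1, with 5253307 matches in all. Each read was put in 1 class by overlap of at least 1 nt with the gene models of the reference, on either strand, in the order miRNA, tRNA with rRNA, snRNA and snoRNA, TAS, TE gene, protein-coding gene, other gene, intergenic and organelle only. Since miRNA comes first, reads at an annotated miRNA gene inside a TE count as miRNA. The reference holds no TE annotation, and 154 gene models are described as transposons. A model was therefore also called a TE gene if it is a pseudogene without a description and has translated similarity to these (tblastx of BLAST+ 2.17.0, E at most 1e-10, at least 50 amino acids), directly (1829 models) or through 1 of these (1664 models). This took 3493 of 3865 undescribed pseudogenes, against 111 of 923 described pseudogenes of other genes and 16 of 547 sampled protein-coding genes, and gave 3647 TE genes among 38312 gene models. This definition departs from the one planned, the annotated TEs and the described models, and was set once the reference had been seen and before reads were counted at loci. Superfamilies come from the description or from direct similarity, so the Athila group holds models similar to those described as Athila and can include other Gypsy elements, while TE genes reached through another model have no superfamily. In counts by superfamily a TE read was counted once in each superfamily it matches. No model named a Gypsy element outside Athila, a Helitron or a SINE, and the non-coding parts of TEs are not covered.

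Counts per locus split each read evenly over its perfect matches and were rounded. Loci, listed small RNAs, distinct sequences and superfamilies were compared between genotypes with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with the total of 18 to 28 nt reads as library size and no further factor, since the question was the share of AGO1-bound RNA. Features were kept by filterByExpr with a minimum count of 10, and p-values were adjusted by Benjamini-Hochberg over the features tested, with a threshold of 0.05. Shares of reads were compared with a two-sided exact permutation test over the 6 libraries, which cannot give a p under 0.1. Lists were tested with camera (preset correlation 0.01 and an estimated correlation) and fry of limma 3.58.1 on log counts scaled to library size. On simulated counts for 3647 loci with a dispersion of 0.03, the locus test called 73 of 76 loci changed by a log2 fold change of 1.5 in the right direction, 103 of 103 changed by 3, and 5 of 3070 unchanged loci. The simulated changes were few and drawn alike in both directions, and the data had a common dispersion of 0.0365. The simulation thus does not test calls under a shift in composition such as that seen here. The lists of 62 small RNA sequences and 34 loci, the tests, the alternatives and the rule for named genes were set before the data were examined, and additions made later are named in the closing section. The sequence list was written from memory of miRBase names, and all 57 of its 58 miRNAs that were seen match an annotated miRNA gene. Named loci were the 10 largest changes in each direction among called loci with no overlap between the genotypes and at least 10 RPM in the higher genotype, the 10 called TE loci with the most reads, and up to 4 members of each fixed list. Further list members were named where an alternative changed their call or direction. Named miRNAs were the 10 most abundant, those called (at most 10 per direction, to which the 1 remaining fall was added), and miR854, miR845a, miR845b, miR168, miR403, miR390 and miR393b-3p whatever their result. Named sequences were the 5 most abundant called in each direction, and all superfamilies were named. A locus with no read in a genotype was given the level that 3 counts in the pooled libraries of that genotype allow. Alternatives were TMM factors, DESeq2 1.42.0 size factors and its Wald test, reads of the listed miRNAs as library size, other filters on low counts, reads with 1 perfect match, distinct sequences, 1 size class alone, 3 other TE definitions, reads outside the miRNA class, and each library left out in turn. Figures were drawn with matplotlib 3.10.9.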

Results

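Small RNAs bound to AGO1, the Argonaute protein that carries most plant miRNAs, were sequenced from unopened flower buds of Arabidopsis thaliana Columbia-0. Libraries came from AGO1 immunoprecipitates of 2 genotypes, with 3 wild-type (WT) libraries and 3 of the genotype labelled ddm1F6. DDM1 is a chromatin remodeler needed for DNA methylation and for silencing of transposable elements (TEs), and the series asked which TE small RNAs enter AGO1. The WT libraries held 6659520, 7185508 and 1769307 reads of 18 to 28 nt, and the ddm1F6 libraries 2266892, 3066317 and 2983330. Values are means ± SD over n = 3 libraries, in percent of reads or in reads scaled to a library of 1000000 reads of 18 to 28 nt (RPM). No read mapped to the DDM1 gene itself (chromosome 5, 26648897 to 26653191) in any of the 6 libraries, where 0 reads allow up to 0.418 to 1.70 RPM, so these small RNAs do not check the genotype. Such limits and intervals cover counting error only.

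The first comparison asked how much of the AGO1-bound RNA came from TEs. TE genes gave 3.41 ± 0.202% of the reads in WT and 34.5 ± 2.23% in ddm1F6. Among reads of 21 and 22 nt, the sizes AGO1 is known to carry, the TE share was 2.18 ± 0.119% in WT and 37.2 ± 3.09% in ddm1F6. The miRNA share was 74.3 ± 0.440% in WT and 44.5 ± 5.83% in ddm1F6. Reads from protein-coding genes made up 4.89 ± 0.104% in WT and 2.80 ± 0.507% in ddm1F6. In each of these 4 shares the 3 libraries of one genotype lay apart from the 3 of the other, with an exact two-sided permutation p = 0.1, the smallest that 3 libraries against 3 can give. The protein-coding share includes reads of AT3G06435. With the 5 kb before it, this gene gave 11660 ± 861 RPM of 22 nt reads alone in WT and 670 ± 317 RPM in ddm1F6. The protein-coding share without this gene was not computed, so its fall does not show a fall over genes in general. Intergenic reads (12.3 ± 0.344% and 13.1 ± 2.10%, exact permutation p = 0.6) and reads of the TAS loci, which make trans-acting siRNAs (1.05 ± 0.214% and 0.864 ± 0.0839%, p = 0.2), overlapped between the genotypes. Among reads of 21 and 22 nt, however, the intergenic share lay apart, at 5.59 ± 0.0496% in WT and 9.06 ± 1.26% in ddm1F6 (exact permutation p = 0.1). Most of the TE genes counted here were recognised by translated similarity to annotated TE genes, and the 154 gene models described as transposons alone gave 0.284 ± 0.0244% of reads in WT and 0.335 ± 0.0400% in ddm1F6 (exact permutation p = 0.2). Over reads with 1 perfect match in the genome, the TE share was 4.95 ± 0.303% in WT and 17.1 ± 0.811% in ddm1F6, and among such reads of 21 and 22 nt 4.28 ± 0.156% and 22.7 ± 0.926%.

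**Figure D1:**
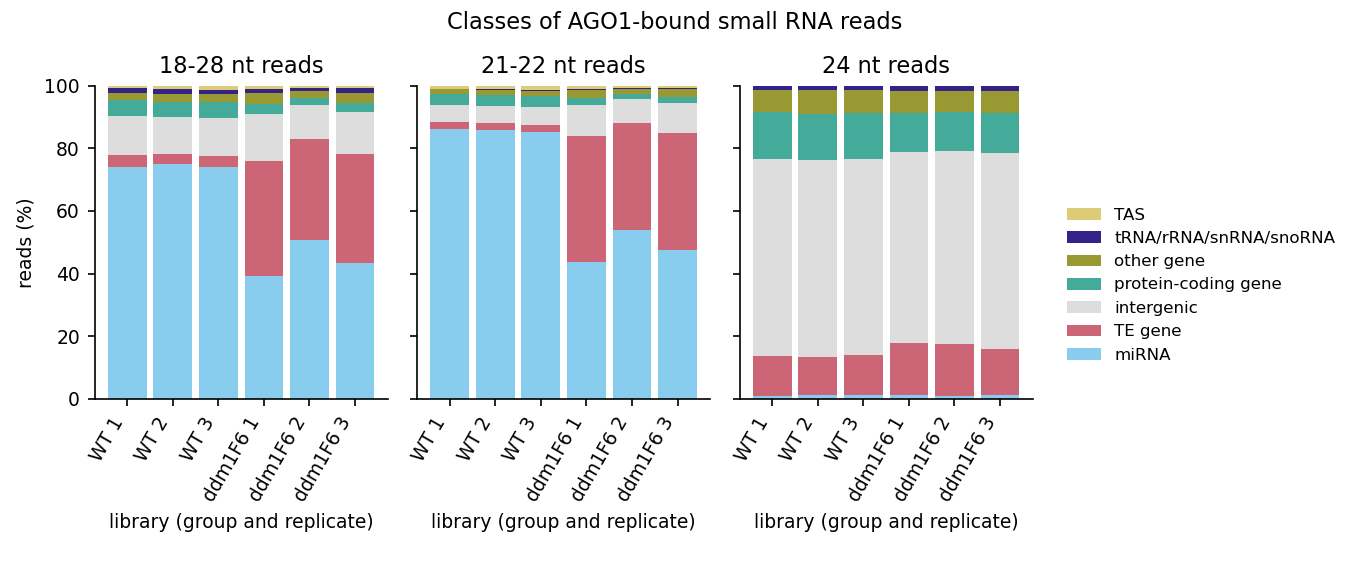
Share of 18 to 28 nt reads (percent, vertical axis) in each class for each of the 6 libraries (horizontal axis). The TE gene class lies at 3.18 to 3.57% in the 3 WT libraries and at 32.2 to 36.7% in the 3 ddm1F6 libraries, and the miRNA class at 74.0 to 74.8% and 39.2 to 50.8%.

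The TE reads of ddm1F6 were of other lengths than those of WT. TE reads of 21 nt stood at 5934 ± 217 RPM in WT and 251672 ± 13186 RPM in ddm1F6, a log2 ratio of 5.41. Those of 22 nt stood at 11368 ± 716 and 63814 ± 3099.9 RPM, a log2 ratio of 2.49. Both size classes lay apart between the genotypes (exact permutation p = 0.1, the smallest possible). TE reads of 24 nt, the size of siRNAs that direct DNA methylation, were at 10775 ± 958 RPM in WT and 9468 ± 2120.3 RPM in ddm1F6, and the libraries overlapped (exact permutation p = 0.5). There were 0.553 ± 0.0371 TE reads of 21 nt for each of 24 nt in WT and 27.2 ± 4.45 in ddm1F6. Of all 24 nt reads, 12.5 ± 0.380% came from TE genes in WT and 15.9 ± 0.990% in ddm1F6 (exact permutation p = 0.1). The order turned over among reads with 1 perfect match (8.69 ± 0.278% and 6.92 ± 0.289%) and when each distinct sequence counted once (19.3 ± 1.13% and 17.2 ± 0.786%). Most 24 nt reads were intergenic, 62.8 ± 0.224% in WT and 61.5 ± 0.688% in ddm1F6. That class can hold TE parts outside the TE genes counted, so the 24 nt values cover only the TE genes.

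The makeup of AGO1 cargo by length and first base was compared next. Reads of 21 nt were the main class in both genotypes, at 69.9 ± 0.947% in WT and 71.6 ± 3.53% in ddm1F6 (exact permutation p = 0.5). Reads of 22 nt made up 9.37 ± 0.278% in WT and 13.3 ± 0.822% in ddm1F6, and reads of 24 nt 8.60 ± 0.534% and 5.97 ± 1.28%, with the genotypes apart in both (exact permutation p = 0.1, the smallest possible). Reads that began with U, the base AGO1 prefers, made up 92.5 ± 0.321% in WT and 86.5 ± 2.85% in ddm1F6 (exact permutation p = 0.1). Of 21 nt reads, those that began with C made up 0.994 ± 0.0332% and 6.29 ± 0.893% (exact permutation p = 0.1). Outside the miRNA class, however, a first C made up 12.6 ± 0.902% and 13.4 ± 0.346% of 21 nt reads (exact permutation p = 0.3), and among 21 nt TE reads 15.6 ± 0.754% and 13.5 ± 0.267% (p = 0.1). Outside the miRNA class, 21 nt reads stood at 18.3 ± 1.01% in WT and 58.8 ± 2.22% in ddm1F6, and 24 nt reads at 33.0 ± 1.69% and 10.5 ± 1.18% (exact permutation p = 0.1 for both). The order of 2 shares turned over outside the miRNA class. Reads of 22 nt were at 25.8 ± 0.0263% in WT and 20.2 ± 0.677% in ddm1F6. Reads with a first U were at 72.7 ± 1.70% and 76.8 ± 2.60% (exact permutation p = 0.2). Reads of 24 nt with a first A, the usual cargo of the AGO4 clade, made up 0.998 ± 0.0521% of reads in WT and 0.614 ± 0.388% in ddm1F6 (exact permutation p = 0.3). Fragments of tRNA, rRNA, snRNA and snoRNA, a sign of unbound RNA, made up 1.53 ± 0.124% and 1.32 ± 0.309% (exact permutation p = 0.4). Reads with any match to the chloroplast or mitochondrial genome made up 0.0748 ± 0.00171% and 0.0634 ± 0.0295%. Outside the class of tRNA, rRNA, snRNA and snoRNA, no read in any library matched an organelle genome alone. Such reads may have been removed before deposit, so the organelle share cannot gauge unbound RNA. Whether tRNA or rRNA fragments were removed as well is not known.

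TE small RNAs were then counted by superfamily, with 21 to 22 nt and 24 nt reads apart. A read with matches in TE genes of several superfamilies was counted once in each, so the superfamilies overlap and their sums exceed the TE reads. Athila, a family of long terminal repeat retrotransposons of pericentromeric heterochromatin, was matched by 36.0 ± 0.966% of the 21 to 22 nt TE reads in WT and 87.9 ± 0.542% in ddm1F6, including reads that match other groups as well. Athila reads of 21 to 22 nt rose from 6236 ± 471 to 277203 ± 14652 RPM (log2 fold change 5.47, adjusted p = 2.4e-12, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the 16 tests of a superfamily in a size class). Copia retrotransposons rose from 1087 ± 19.0 to 5250.0 ± 363 RPM (log2 fold change 2.27, adjusted p = 7.7e-08). The En-Spm (CACTA) DNA transposons rose from 984 ± 31.6 to 3888 ± 648 RPM (log2 fold change 1.98, adjusted p = 1.3e-06). TE genes with no superfamily assigned rose from 8449 ± 435 to 82990.0 ± 4206 RPM. Mutator DNA transposons fell from 618 ± 28.3 to 388 ± 54.0 RPM (log2 fold change -0.67, adjusted p = 0.0017). The Mutator call was lost with TMM factors (log2 fold change -0.18) and turned over with miRNA reads as library size (0.15). Sadhu retroelements rose by 0.30 and hAT transposons fell by 0.33 on the log2 scale. Both calls were lost without any 1 of the WT replicates, that of Sadhu also without ddm1F6 replicate 1. In those fits the log2 fold changes stayed at 0.27 to 0.31 for Sadhu and -0.34 to -0.32 for hAT. With TMM factors hAT turned to 0.17, and with miRNA reads as library size to 0.48. LINE retrotransposons, at 1493 ± 42.3 RPM in WT and 1254 ± 144 RPM in ddm1F6, did not pass (adjusted p = 0.11), but did without ddm1F6 replicate 3 (log2 fold change -0.34) and over reads with 1 perfect match (-0.43). In the 24 nt class Mutator fell most, from 548 ± 54.5 to 179 ± 30.7 RPM (log2 fold change -1.62, adjusted p = 7.7e-06). With it fell Copia (-1.02), hAT (-0.97), LINE (-0.86) and Sadhu (-0.73), as log2 fold changes. With miRNA reads as library size these 4 calls were lost (Copia -0.18, hAT -0.13, LINE -0.0275 and Sadhu 0.10), and that of Sadhu also with TMM factors (-0.23) and over reads with 1 perfect match (-0.35). Athila reads of 24 nt rose from 1938 ± 231 to 2859.7 ± 707 RPM (log2 fold change 0.56, adjusted p = 0.021), a call lost without WT replicate 2, where the log2 fold change was 0.47. En-Spm and the TE genes with no superfamily did not pass at 24 nt (adjusted p = 0.65 and 0.25). En-Spm at 24 nt had a log2 fold change of -0.0895, or 0.39 with TMM factors and 0.75 with miRNA reads as library size, but was called lower over reads with 1 perfect match (-1.27). TE genes with no superfamily had 0.21 at 24 nt and were called higher with TMM factors (0.70) and with miRNA reads as library size (1.04), but stood at -0.73 over reads with 1 perfect match. Of these 16 tests, 13 passed, and 14 over reads with 1 perfect match. There the log2 fold change of Copia at 21 to 22 nt was -0.0806 and that of Athila at 24 nt -1.01, opposite in sign to the rises above.

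**Figure D2:**
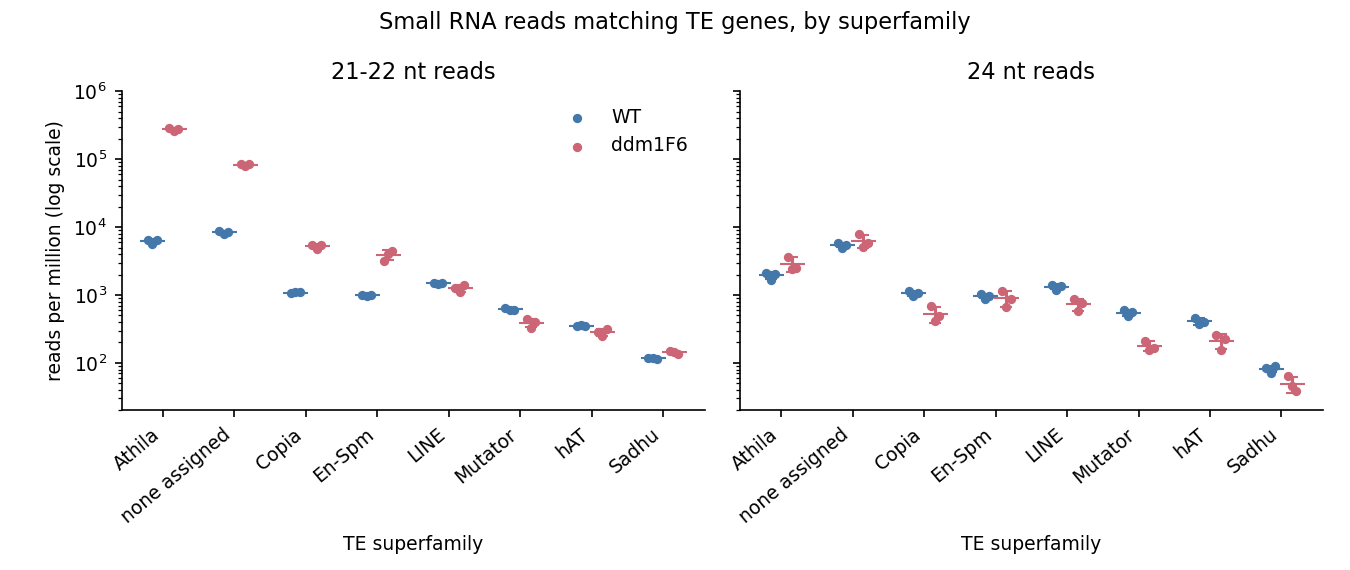
RPM (log scale, vertical axis) of each TE superfamily (horizontal axis) for 21 to 22 nt and 24 nt reads, with points for the 3 libraries of each genotype and the mean and SD of each group, a read counting in every superfamily it matches. Athila at 21 to 22 nt lies at 5692 to 6517 RPM in WT and 262120.0 to 291382 RPM in ddm1F6. Mutator is lower in ddm1F6 at both sizes, with the order at 21 to 22 nt turning over when miRNA reads are the library size.

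Along the chromosomes, the 21 to 22 nt reads outside the miRNA class gathered in ddm1F6 near the centromeres. Of the 500 kb bins of the TAIR10 genome, chromosome 5 from 11500001 to 12000000 held the most such reads in ddm1F6, at 93806 ± 4919 RPM against 829 ± 84.7 RPM in WT. In WT the bin with the most 21 to 22 nt reads was on an arm, at chromosome 3 from 1500001 to 2000000, with 15208 ± 1203 RPM in WT and 955 ± 377 RPM in ddm1F6. For 24 nt reads the highest WT bin was chromosome 3 from 15500001 to 16000000, with 1808 ± 175 RPM in WT and 690.1 ± 118 RPM in ddm1F6. These bins were picked by their height and were not tested.

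**Figure D3:**
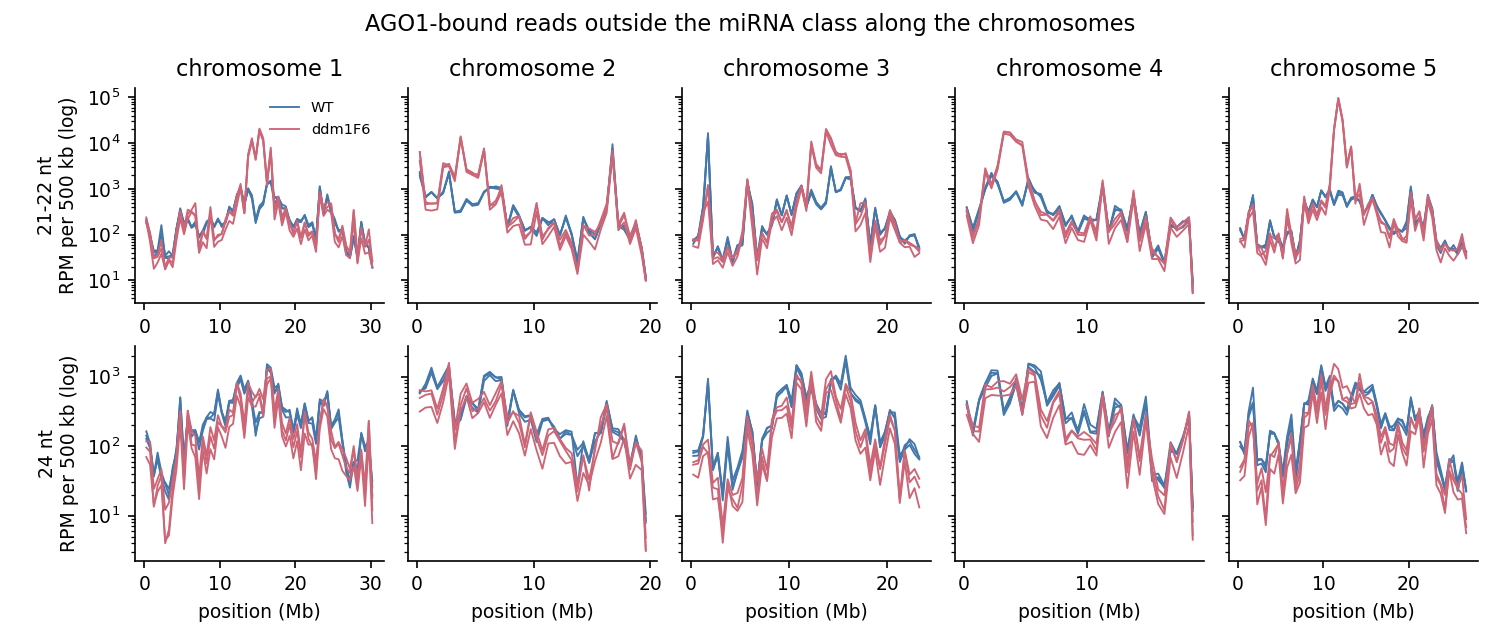
RPM in 500 kb bins (log scale, vertical axis) along the 5 chromosomes (position in Mb, horizontal axis) for 21 to 22 nt and 24 nt reads outside the miRNA class, with 1 line per library coloured by genotype and values under 1 RPM drawn at 1. The highest 21 to 22 nt bin of ddm1F6, on chromosome 5, has a mean of 93806 RPM against 829 RPM in WT.

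Reads were then counted per annotated locus, each read split evenly over its perfect matches, so counts of copies that share reads do not show which copy made them. The leading Athila sequence, for one, matches AT5G29975, AT5G31719, AT5G32107, AT5G32197, AT5G32228 and AT5G32306 alike. Athila copies had the most reads of the TE loci called. AT5G29975 (chromosome 5, 11323981 to 11329884) rose from 107 ± 10.5 to 16467 ± 891 RPM. AT5G32306 (chromosome 5, 11941158 to 11943053) rose from 66.9 ± 10.3 to 15469.8 ± 975 RPM and AT5G31719 (chromosome 5, 11689260 to 11692220) from 87.4 ± 8.31 to 15065 ± 1022 RPM. The 10 called TE loci with the most reads, these 3 with AT5G32228, AT5G32107, AT5G32197, AT4G06517, AT5G32511, AT2G09187 and AT3G33067, are all Athila-like and 7 of them lie on chromosome 5 between 11323981 and 12144657. Together they took 0.0681 ± 0.00693% of reads in WT and 11.3 ± 0.662% in ddm1F6, and their log2 fold changes ran from 6.38 to 7.90, each with an adjusted p of 4.1e-15 or less. The largest rise was at the Athila copy AT4G06664 (chromosome 4, 3869799 to 3871808), from 4.58 ± 0.937 to 1612 ± 191 RPM (log2 fold change 8.53 ± 0.27 SE, adjusted p = 3.1e-15). Among the next were AT4G06712 (4.78 to 1529 RPM) and the undescribed pseudogenes AT2G07580 (1.38 to 472 RPM) and AT2G07590 (0.624 to 177 RPM). MIR854b, MIR854d and MIR854e, annotated miRNA genes that lie inside the Athila copies AT5G29975, AT5G31719 and AT5G32306, rose from 4.13, 3.90 and 3.90 to 1309, 1200.3 and 1200.3 RPM, and share reads with each other. One rise among the 10 largest was at a protein-coding gene, the homeobox gene HB21 (AT2G02540, chromosome 2, 683625 to 685496), with 2 reads in WT and 364 in ddm1F6, a ratio of 342 with an exact 95% counting interval of 93.9 to 2832.

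The 10 largest falls were loci with no read in any ddm1F6 library, so their folds are lower bounds against 3 counts over the pooled ddm1F6 libraries (0.361 RPM). AT4G03830, a protein-coding gene (chromosome 4, 1790440 to 1792458), held 37.7 ± 7.70 RPM in WT and was at least 104-fold lower (adjusted p = 3.0e-10). Its neighbour AT4G03835, a TE gene (chromosome 4, 1793326 to 1795289), held 18.4 ± 3.18 RPM and was at least 50.9-fold lower. The TE genes AT3G43680, AT5G28637, AT5G26775, AT2G16820 and AT1G17900 and the pseudogenes AT2G13710, AT5G28200 and AT2G13706 were at least 43.1-fold to 77.8-fold lower. Of 3647 loci tested, 919 were higher and 1947 lower in ddm1F6 at an adjusted p under 0.05, that is 32.1% of the called loci higher, and with TMM factors 1200 and 1621 (42.5% higher). Of 1783 TE loci, 622 were higher and 901 lower, and with TMM factors 725 and 811. With the reads of the fixed miRNA list as library size the order turned over, to 1236 loci higher and 981 lower, and to 740 TE loci higher and 507 lower. That setting also left fewer loci past the filter on low counts (3012 against 3647), with 48 Mutator loci tested against 91 and 118 Copia loci against 163. The largest part of that library size is the miRNA miR166, at 424449 RPM in WT and 208124 RPM in ddm1F6. Since miR166 is itself among the small RNAs called lower, its fall raises every other feature under that setting. TMM factors moved the median log2 fold change of all loci by 0.48, from -0.83 to -0.34. The 3 libraries of one genotype lay apart from the other 3 at 2744 of the 2866 called loci and at 78.1% of those tested, against 10% by chance.

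The superfamilies, as fixed lists of loci, moved in different directions. Of the Athila loci, 138 of 186 were higher and 43 lower (median log2 fold change 3.93, 4.44 with TMM factors, camera adjusted p = 3.3e-26, adjusted p = 0.79 with an estimated correlation). Of the En-Spm loci, 70 of 127 were higher and 46 lower (median 1.54, 2.03 with TMM factors, camera adjusted p = 3.2e-05, adjusted p = 0.92 with an estimated correlation). Copia loci were mostly lower, 127 of 163 against 21 higher (median -2.67, -2.20 with TMM factors, camera adjusted p = 3.9e-04, adjusted p = 0.92 with an estimated correlation), although the Copia reads of 21 to 22 nt rose as a sum. LINE loci were lower at 133 of 183 and higher at 11 (median -1.83, -1.35 with TMM factors, camera adjusted p = 1.8e-04, adjusted p = 0.92 with an estimated correlation). Mutator loci were lower at 77 of 91 and higher at 10 (median -4.09, or -3.52 with the 30 members without reads in a genotype set at their bound, camera adjusted p = 2.6e-06, adjusted p = 0.79 with an estimated correlation). The hAT list (2 higher, 18 lower of 25) and the Sadhu list (1, 7 of 10) did not pass camera (adjusted p = 0.15 and 0.56). TE loci with no superfamily, 369 higher and 450 lower of 998, had a median of -0.30, or 0.19 with TMM factors, and an upward camera call (adjusted p = 0.033, adjusted p = 0.92 with an estimated correlation) that TMM factors ended. Adjusted over the list alone, the counts of each superfamily list with a name were the same, and the list with no superfamily had 372 higher and 452 lower. These camera tests used a preset correlation of 0.01, and with a correlation estimated from the data none of the 17 lists passed. Fry, which tests each list by itself and not against the other loci, called Athila and En-Spm higher (adjusted p = 4.7e-05 and 0.0023). It called Copia, LINE, Mutator, Sadhu and hAT lower (adjusted p = 4.9e-04, 4.9e-04, 3.0e-05, 5.8e-04 and 0.0028). For the list with no superfamily its direction was down, without a call (adjusted p = 0.12). Of the other lists it called only tRNA, as lower (adjusted p = 0.019). Among 578 TE loci tested in both size classes, 148 were higher in both, 240 lower in both, and 61 higher in 21 to 22 nt and lower in 24 nt reads. The 123 Athila loci among them had a median log2 fold change of 4.52 in 21 to 22 nt and -1.03 in 24 nt reads.

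**Figure D4:**
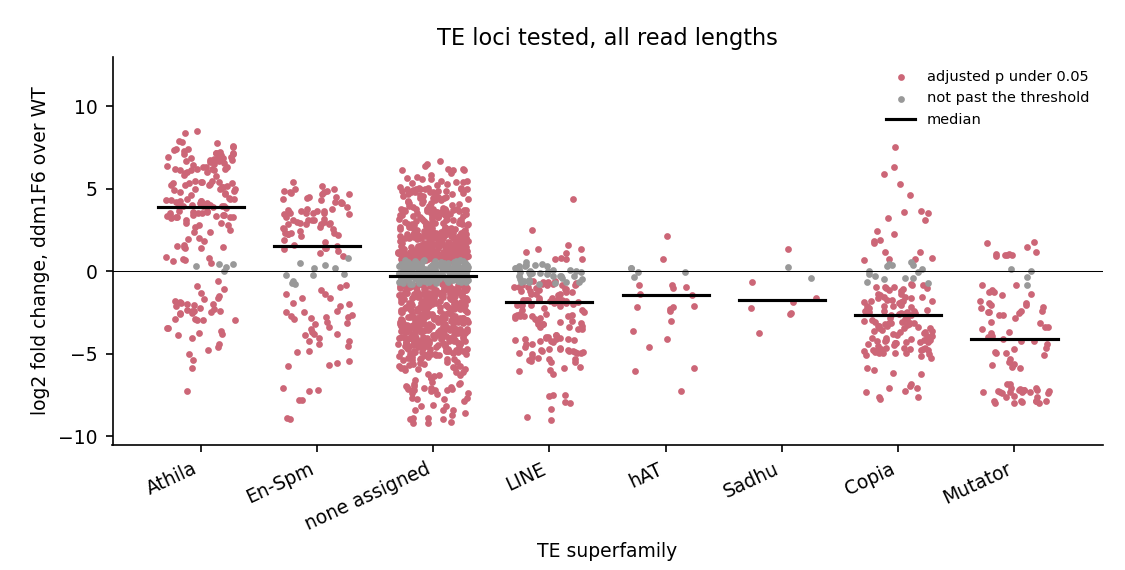
Log2 fold change, ddm1F6 over WT (vertical axis), of each tested TE locus by superfamily (horizontal axis), with loci at an adjusted p under 0.05 in red, the others in grey and the median as a black line. The Athila median lies at 3.93 and the Mutator median at -4.09, and the median of loci with no superfamily, at -0.30, turns positive with TMM factors and with miRNA reads as library size.

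Lists of endogenous loci that make secondary siRNAs through miRNA cleavage were checked alongside. None of the 7 TAS loci tested passed the threshold in the edgeR test, nor when adjusted over the list alone. TAS1C was at 5139.6 ± 1197 and 3988 ± 446 RPM, TAS2 at 3175 ± 696 and 2605 ± 264 RPM and TAS3 at 1187 ± 99.4 and 1269 ± 128 RPM. At an unadjusted p under 0.05, 1 of the 7 passed, TAS3b (698 ± 115 and 516 ± 84.1 RPM), and 2 passed as higher in the DESeq2 Wald test and with TMM factors, TAS3 and TASIR-ARF. TAS1B, TAS1C and TAS3b were called lower without ddm1F6 replicate 1 (log2 fold changes -0.53, -0.46 and -0.49), TAS1C also without WT replicate 1 (-0.52), and TASIR-ARF higher without ddm1F6 replicate 2 (0.72). Over 24 nt reads alone TAS1C and TAS2 were called lower (-1.04 and -0.78). With miRNA reads as library size TAS2 turned to 0.53, and TAS3 and TASIR-ARF were called higher (0.92 and 1.30). Of 15 pentatricopeptide repeat (PPR) loci tested, 2 were lower, also adjusted over the list alone: AT5G16640 (15.4 ± 0.815 to 7.23 ± 2.31 RPM) and AT1G63230 (5.81 ± 1.44 to 2.65 ± 0.367 RPM), and neither passed with TMM factors. The PPR loci with most reads, AT1G63150 (76.6 and 61.8 RPM) and AT1G63080 (74.6 and 66.5 RPM), did not pass. Both auxin receptor genes tested, AFB2 (7.36 ± 0.521 to 4.17 ± 1.65 RPM) and AFB3 (16.1 ± 4.59 to 8.82 ± 1.55 RPM), were lower, also adjusted over the list alone (log2 fold changes -0.87 and -0.95). Neither passed with TMM factors (-0.39 and -0.47) or without WT replicate 2 (-0.82 and -0.73), nor AFB2 without ddm1F6 replicate 2 (-0.55). Of 3 silencing genes that make siRNAs, AGO2 was lower (173 ± 21.6 to 93.8 ± 10.8 RPM, adjusted p = 0.0011), but it did not pass with DESeq2 size factors or miRNA reads as library size, nor over reads with 1 perfect match, where its log2 fold change was 0.18. AGO1 (14.9 and 15.8 RPM) and DCL1 (22.3 and 22.6 RPM) did not pass, and both were called higher with TMM factors. Camera called none of these 4 lists (adjusted p = 0.94 to 0.95). Among the lists for RNA quality, 4 of 5 rRNA genes were higher and both tRNA genes tested lower. Of 11 mitochondrial genes, 2 were higher and 3 lower, and 1 of 3 chloroplast genes, psbA, was lower, a call that did not hold when adjusted over the list alone. Of 157 miRNA loci, 26 were higher and 71 lower, or 25 and 68 adjusted over the list alone, and with TMM factors 40 and 24.

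The canonical cargo of AGO1, its miRNAs, was compared by exact sequence from a list fixed beforehand. miR166, which targets the class III HD-ZIP genes, was the most abundant, and fell as a share of AGO1 reads from 424449 ± 10814 to 208124 ± 40438 RPM (log2 fold change -1.03 ± 0.17 SE, adjusted p = 0.0052). The related miR165 stood at 124012 ± 5794 and 96279 ± 26098 RPM and did not pass (adjusted p = 0.21), but was called lower without ddm1F6 replicate 2 (log2 fold change -0.59) and higher with miRNA reads as library size (0.40). miR825 (4.15 to 0.626 RPM, log2 fold change -2.70), miR846 (-1.73), miR396a, which targets growth-regulating factors (559 ± 96.5 to 177 ± 44.3 RPM), miR822 (-1.04) and miR393b-3p, a strand known as AGO2 cargo (9.25 ± 2.68 to 2.98 ± 0.917 RPM), fell as well. miR393b-3p no longer passed when reads with up to 2 nt added or missing at the 3′ end were counted (log2 fold change 0.36). miR396b (6169.6 ± 659 to 3680.4 ± 80.3 RPM), miR156 (555 ± 14.8 to 348 ± 76.6 RPM), the DCL1 regulator miR162 (8946 ± 1544 to 5893 ± 645 RPM), the AGO2 regulator miR403 (3541 ± 539 to 2418 ± 139.7 RPM) and miR319 (2983 ± 45.5 to 2046 ± 124 RPM) fell with total reads as library size, but their log2 fold changes were 0.0572 to 0.26 with miRNA reads as library size. The largest rise was in miR843, from 2.50 ± 0.740 to 322 ± 109 RPM (log2 fold change 6.90 ± 0.40 SE, adjusted p = 1.4e-05). miR447a rose from 6.18 ± 2.16 to 22.6 ± 6.95 RPM and miR823, which targets the DNA methyltransferase gene CMT3, from 8.29 ± 1.58 to 18.8 ± 5.60 RPM (log2 fold changes 1.93 and 1.20). Other abundant miRNAs did not pass: miR158a (33986 ± 9972 and 21696 ± 539 RPM, adjusted p = 0.052, but called lower without WT replicate 1 or ddm1F6 replicate 2), miR159b (21567 ± 976 and 16582 ± 3183 RPM), miR159a (19453 ± 1618 and 15831 ± 4833 RPM) and miR161.1 (2336 and 2288 RPM). The AGO1 regulator miR168 (1337 ± 625 and 1101 ± 147 RPM) and the AGO7 cargo miR390 (97.8 ± 21.7 and 79.7 ± 28.9 RPM) did not pass either. Nor did miR845a (6.81 ± 3.52 and 4.39 ± 2.42 RPM) and miR845b (9.04 ± 1.49 and 5.48 ± 1.08 RPM), which match primer binding sites of retrotransposons. The annotated miR854 sequence had 0 reads in WT and 4 in ddm1F6 and was not tested. Of 48 listed small RNAs tested, 3 were higher and 11 lower (edgeR, adjusted p under 0.05). The split depended on the scaling: with TMM factors 8 were higher, among them miR164, miR398 and miR408, and 4 lower, miR825, miR846, miR396a and miR393b-3p but not miR166. With miRNA reads as library size 8 were higher and 1 lower, miR166, of 47 tested, since miR825 fell under the low count filter there. The largest part of that library size is miR166 itself, so that scale is not independent of its fall. With reads of up to 2 nt added or missing at the 3′ end, 15 were lower, among them miR158a, miR159a (-0.83), miR159b (-0.86), miR171b-c (-0.98) and miR391 (-0.82, as log2 fold changes), which did not pass by exact sequence. Left out 1 at a time, no library ended the calls of miR843, miR166, miR396a, miR396b and miR825. The call of miR403 was lost without any 1 of the 6 libraries (log2 fold changes -0.63 to -0.42), those of miR156, miR822 and miR823 in 5 of the 6 fits (-0.87 to -0.57, -1.19 to -0.89 and 1.03 to 1.44 over the 6) and those of miR162 and miR846 in 4 (-0.73 to -0.48 for miR162). In the fits that lost it, miR846 stood at -1.67 to -1.37. The calls of miR319 and miR393b-3p were lost in 3 fits (-0.58 to -0.50 for miR319 over the 6, and -1.53 to -1.42 for miR393b-3p in those 3), and that of miR447a without WT replicate 2 (1.92). Single libraries moved the split too, to 1 higher and 5 lower without WT replicate 2, 2 and 4 without WT replicate 3, 2 and 7 without ddm1F6 replicate 1 and 8 and 9 without ddm1F6 replicate 2.

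**Figure D5:**
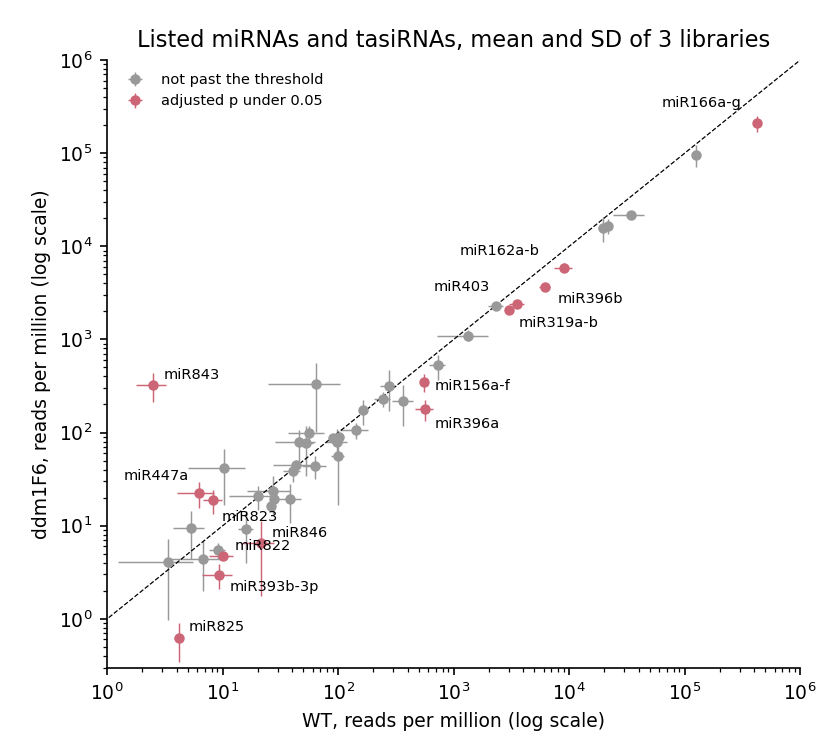
RPM in WT (horizontal axis, log scale) and ddm1F6 (vertical axis, log scale) of each listed miRNA and tasiRNA tested, as the mean and SD of 3 libraries, with those at an adjusted p under 0.05 in red and the dashed line marking equal levels. miR843 lies above the line, at 2.50 and 322 RPM, and miR166 below it with each scaling, at 424449 and 208124 RPM.

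At the level of single small RNAs, 4 of the 5 most abundant sequences that rose in ddm1F6 were 21 nt Athila small RNAs. TGGCGCTCAACTCTGCAAGGT rose from 4.78 ± 1.28 to 10637 ± 1685 RPM (adjusted p = 2.2e-17), with 6 perfect matches, all in Athila genes, the first at chromosome 5, 11325197 to 11325217. TTGGCGCTCAACTCTGCAAGG, offset from it by 1 nt (chromosome 5, 11325198 to 11325218), rose from 2.21 ± 1.29 to 4918 ± 996 RPM. TCCCCAGAAGTCGTTCAGCTC (11 matches in Athila genes, the first at chromosome 2, 3641412 to 3641432) rose from 11.4 ± 0.738 to 6584 ± 1834 RPM. TTCGAGGAGATATGACGCGCC (27 matches in Athila genes, the first at chromosome 1, 13774482 to 13774502) rose from 22.9 ± 9.30 to 4994 ± 710.5 RPM. TTGATCCAAGTAGCTGACTCT rose from 0.713 ± 0.227 to 4121 ± 511 RPM and matched 17 intergenic places, the first at chromosome 1, 15044058 to 15044078. The most abundant sequences that fell were miR166 (above), the 20 nt sequence TTTGGATTGAAGGGAGCTCT, which is miR159 without its last base (10459 ± 1948 to 1391 ± 336 RPM, log2 fold change -2.91), and miR158a, miR162 and miR396b. The calls of miR158a and miR162 in this test were each lost without any 1 of 4 of the libraries (log2 fold changes -0.82 to -0.39 and -0.73 to -0.48 over the 6), that of miR166 without ddm1F6 replicate 1 or 3 (-0.91 and -0.99) and that of miR396b without ddm1F6 replicate 3 (-0.73). Of 14475 sequences tested, 8782 were higher and 2793 lower. Among those of 21 nt, 5528 of 6572 were higher and 441 lower, among those of 22 nt 2081 and 717 of 3598, and among those of 24 nt 524 and 1168 of 2745. With miRNA reads as library size, the 5 rises kept their direction, while miR158a, miR162 and miR396b turned positive (0.0572 to 0.20 on the log2 scale). The sequence of miR166 stood at -0.25 there and was no longer called in this test.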

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

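The test of the reads of 16 and 17 nt was chosen only after the shares of longer reads were seen. These reads, 1.33 ± 0.358% of the deposited reads in WT and 0.913 ± 0.119% in ddm1F6, were left out of the comparisons, and stood out because TE genes gave more of them in ddm1F6 than in WT. The TE share of 16 and 17 nt reads was 2.12 ± 0.641% in WT and 35.5 ± 1.48% in ddm1F6, with a mean of 35.52% (n = 3, exact two-sided permutation p = 0.1, the smallest possible).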

How the results depend on the processing

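The alternative TE definitions and the shares outside the miRNA class were chosen only after the data were seen. Of the results that answer a comparison, 186 values under an alternative were shares that kept their direction or counts that stayed within 1.5 times, 36 were counts that moved further and 7 were shares that turned over, and of those for named genes, sequences and superfamilies 1579 kept direction and call, 130 lost the call, 71 gained one and 25 turned over, and the cause was not tested. Shares that kept direction did not all stay close: with TE genes named by description the difference of the TE share was 0.0507 percentage points, 0.0586 among 21 to 22 nt and 0.188 among 24 nt reads, and over distinct sequences 15.1 and 20.5 for all and 21 to 22 nt reads, 12.5, 0.00523 and -9.34 for the 21, 22 and 24 nt shares. Over reads with 1 perfect match the TE share differed by 12.1 and 18.4 points for all and 21 to 22 nt reads, and outside the miRNA class by 49.1 and 56.9, the 21 nt share by 40.4 and the 24 nt share by -22.5. Differences that turned over, ddm1F6 minus WT in percentage points, were those of the TE share of 24 nt reads over distinct sequences (-2.03) and over reads with 1 perfect match (-1.77), the 22 nt share outside the miRNA class (-5.57), the first U share over distinct sequences (0.241) and outside the miRNA class (4.12), the miRNA share over distinct sequences (0.287) and the 21 nt share without ddm1F6 replicate 2. With 1 library left out, differences ran over 33.6 to 36.7 for the TE share of 21 to 22 nt reads, 3.05 to 3.94 for that of 24 nt reads, -0.144 to 3.37, 3.57 to 4.36 and -3.25 to -1.97 for 21, 22 and 24 nt reads, -7.35 to -4.50 for the first U and -33.0 to -27.2 for miRNA. Counts ran over 893 to 1081 loci higher and 1920 to 2216 lower, 606 to 673 and 871 to 1033 TE loci, 1 to 8 and 4 to 10 miRNAs, 9601 to 12063 and 2885 to 3919 sequences and 10 to 14 superfamily tests. With miRNA reads as library size, where 3012 loci passed the filter on low counts against 3647 with total reads, 981 loci, 507 TE loci, 1 miRNA and 1132 sequences were lower and 8 miRNAs higher, and with no filter on low counts 3247 loci, 1486 TE loci, 5 miRNAs and 7850 sequences were lower and 26169 sequences higher. miRNAs higher and lower were 8 and 4 with TMM factors, 7 and 4 with DESeq2 size factors in edgeR and 7 and 3 with the DESeq2 Wald test. Over reads with 1 perfect match 445 loci and 279 TE loci were higher and 600 TE loci lower, over 21 to 22 nt reads 854 loci and 402 TE loci lower, and over 24 nt reads 284 and 768 loci and 170 and 375 TE loci higher and lower. TE loci named by description were 5 higher and 20 lower, and by description or direct similarity 357 and 572. With an estimated correlation camera called 0 lists, against 6 with the preset one and 5 with TMM factors. Log2 fold changes that turned over with miRNA reads as library size were those of AT1G62590 (0.78), TAS2 (0.53), miR156 (0.16), miR162 (0.20, also as a sequence), miR165 (0.40), miR319 (0.25), miR396b (0.0572, also as a sequence), miR403 (0.26), the sequence of miR158a (0.16), hAT (0.48) and Mutator (0.15) at 21 to 22 nt, and En-Spm (0.75) and Sadhu (0.10) at 24 nt. AT1G62590 also turned with TMM factors (0.47) and DESeq2 size factors (0.47), and with TMM factors hAT at 21 to 22 nt (0.17) and En-Spm at 24 nt (0.39). Over reads with 1 perfect match AGO2 (0.18, and 0.11 over 21 to 22 nt reads), Copia at 21 to 22 nt (-0.0806), and Athila (-1.01) and TE genes with no superfamily (-0.73) at 24 nt turned over, as did miR393b-3p counted with 3′ end variants (0.36). The replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.0249, -0.0387 and 0.000202), and with the number as a block 874 loci were higher and 1900 lower, 607 and 882 TE loci, 6 and 12 miRNAs and 8583 and 2615 sequences, with 13 superfamily tests and 6 lists past the threshold. Keeping only sequences with a perfect match removed none, and an alternative with TE fragments beside TE genes gave no value because the annotation holds no fragments.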

Other observations

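Every value in the first 3 paragraphs here, and the tests of the miRNA share, unbound RNA, depth, a repeat family and other splits, were chosen only after the results were seen. The fits over reads with 1 perfect match and with other scalings were planned, but the bounds that decide on them were set afterwards. The 500 kb bin with the most 21 to 22 nt reads in WT holds AT3G06435, annotated as protein-coding (chromosome 3, 1968288 to 1970946). It had 7005 ± 589.7 RPM in WT and 412 ± 192 RPM in ddm1F6 (log2 fold change -4.09, adjusted p = 3.3e-10). Over the gene and the 5 kb before it, 80.7% of WT reads matched both strands of the region. Reads of 22 nt there were at 11659.7 ± 861 RPM in WT and 669.8 ± 317 RPM in ddm1F6, and made up 17.2% of the 22 nt reads of WT outside the miRNA class. Reads of 21 nt were at 3453 ± 370.0 and 208 ± 69.7 RPM, and reads of 24 nt at 779 ± 80.6 and 43.6 ± 20.6 RPM, so that WT levels were 16.6 to 18.2 times those of ddm1F6 over lengths of 21 to 24 nt (exact permutation p = 0.1 each, the smallest possible). The leading sequence, TGACGAGAGAACTTATTGGCCT, stood at 2456 ± 194 RPM in WT and at 69.7 to 244 RPM in the 3 ddm1F6 libraries and matches chromosome 3 at 1964889 to 1964910 on the plus strand and at 1969260 to 1969281 on the minus strand.

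Single TEs known to be controlled by DDM1 were looked up. EVADE, an active Copia element (chromosome 5, 5630538 to 5634764), had 2.90 ± 0.686 RPM in WT and 236 ± 90.8 RPM in ddm1F6 (exact permutation p = 0.1). AtMu1, a Mutator element (chromosome 4, 5542431 to 5544862), had 42.5 ± 4.51 and 0.770 ± 0.505 RPM (exact permutation p = 0.1), and CACTA1, an En-Spm element (chromosome 2, 4902163 to 4908827), 4.83 ± 0.248 and 2.67 ± 3.55 RPM (p = 0.4). The annotated miRNA genes MIR854, MIR5029 and MIR5639 took 0.00448 ± 0.000728% of reads in WT and 1.08 ± 0.158% in ddm1F6. TGACGGACAAGATAAGTTGCT, at MIR854b, MIR854d and MIR854e, was at 0.853 ± 0.467 and 1529 ± 127 RPM, and TCGGGAATGAGAGAGAACACT, at MIR5029, at 14.3 ± 2.78 and 3716 ± 463 RPM.

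The 20 nt forms of 21 nt miRNAs made up a lower share of the 20 and 21 nt reads of the miRNA in every ddm1F6 library for 11 of 16 listed miRNAs with at least 100 RPM. For a single miRNA chance gives 5% in each direction. The 16 come from the same 6 libraries and some share a 20 nt form, so they are not independent and can move together. miR843, 1 of the 16, could not be compared, since WT held 43 reads of it. For miR159a, with the form it has in common with miR159b, the share was 34.9 ± 4.68% in WT and 8.79 ± 4.48% in ddm1F6. For miR167 it was 59.4 ± 2.85% and 26.9 ± 20.8%, and for miR396b, with the form in common with miR396a, 10.1 ± 0.958% and 3.25 ± 0.677%.

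The TE share of 21 to 22 nt reads was higher in ddm1F6. A few abundant sequences cannot account for all of it, since the difference was 24.9 percentage points without the 100 leading TE sequences. Reads with several matches are argued against as the whole cause, since it was 18.4 points over reads with 1 perfect match. Reads of that kind, however, were only 33.5 to 36.6% of 18 to 28 nt reads in WT and 25.6 to 32.0% in ddm1F6. How much of the difference over all reads came from reads with several matches was not computed. A lower miRNA share raising every other class alike would leave the TE share of the other 21 to 22 nt reads as it was, but it differed by 56.9 points. More unbound RNA cannot be ruled out by structural RNA fragments. Their share in ddm1F6 was 0.859 times that in WT, but most of them were snRNA and snoRNA (1.42 ± 0.113% in WT and 1.14 ± 0.255% in ddm1F6). Fragments of rRNA went the other way, at 0.105 ± 0.0169% and 0.167 ± 0.0514% (exact permutation p = 0.2). Whether some structural RNA fragments were removed before deposit is not known. The pattern may follow the genotype, a hypothesis found and tested on the same data, and how much TE siRNA the buds held in total was not measured here.

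More TE loci were lower than higher in ddm1F6, with 1.45 times as many lower. Reads shared between copies are argued against, since the ratio was 2.15 over reads with 1 perfect match. Scaling to total reads stays open, since the ratio was 1.12 with TMM factors and 0.685 with miRNA reads as library size, and no spike-in sets the scale. With miRNA reads fewer loci also passed the filter on low counts (3012 against 3647), so that ratio does not reflect the scale alone. The largest part of the miRNA reads is miR166, which was itself called lower with total reads as library size.

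Of 1554 loci with at least 10 RPM in WT, 24 had no ddm1F6 read, 16 of them TE genes, and 0 loci showed the opposite. Depth as the whole cause is argued against, since even the lowest WT library of each locus would give at least 70.6 reads in the pooled ddm1F6 libraries, where 0 were seen. A single repeat family counted at many loci is argued against as the whole cause, since 15 of the 24 take most of their WT reads from sequences with 1 perfect match. Among these 15, AT2G05465 and AT2G05485 overlap and are not separate places. The remaining loci, all TE genes, took 9.76 to 49.9% of their WT reads from such sequences, so a shared family stays open for them. A deletion or variant in the ddm1F6 plants cannot be told apart from a loss of the small RNAs: 20 of the loci had ddm1F6 reads with 1 perfect match within 2 kb and 4 had none, which leaves room for a deletion of the locus alone.

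A hypothesis that Athila siRNAs come from double-stranded precursors needs reads from both strands. The antisense share of 21 nt reads at Athila genes was 51.1 ± 0.529% in WT and 39.1 ± 0.278% in ddm1F6, and its lowest value over the ddm1F6 libraries was 38.8%. Reads from both strands, which such precursors need, were thus present over the Athila genes as a set. The share pools all these genes, so loci with reads from a single strand each could average to the same value. It does not show both strands at any single locus, or how such precursors form.

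The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of these 10, called 2866 loci, 1523 TE loci, 14 miRNAs, 11575 sequences and 13 superfamily tests, and the highest of the other splits called 0 of each.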
